A study of Caenorhabditis elegans with 4 samples.

How the data were processed

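Whole young adult animals of 2 C. elegans strains were compared, with 2 libraries each. Per the labels' protocols, animals were synchronized by 20 h of arrest at the first larval stage, fed Comamonas aquatica DA1877, and collected 70 h after hatching at 20 °C, and total RNA was extracted with Trizol, treated with DNase and cleaned on columns. The labels name the libraries of a strain as biological replicates but do not say how the cultures were separated, so p-values measure the spread between these libraries, which may be partly technical.

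The deposited values are FPKM per gene with 2 decimals, per the file headers, 1 file per library with the same 20535 genes. Per the submitters' processing notes, Bowtie2 and RSEM were used; their versions, the genome build, the annotation and the strandedness of the libraries are not given in the sources used here. FPKM already divides by transcript length and library total, and no further normalization between libraries is recorded. RSEM shares reads among similar genes by a model, so values of multigene families, of near-identical copies and of pseudogenes are uncertain, and so are those of overlapping genes on opposite strands. The plan, fixed before the data were examined, was a count test on expected counts; because the files hold FPKM, the fallback written in that plan was used.

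Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model with group only, empirical Bayes with a mean-variance trend, 2 residual degrees of freedom per gene and 4.65 prior ones), mutant minus control, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is on the log2(FPKM + 1) scale and understates the change of low genes; folds stated as such are ratios of mean FPKM. Genes with at least 1 FPKM in at least 2 libraries were tested. The plan gave no FPKM filter. This one was chosen after 16 fits had been seen, which crossed 4 filters (none, 0.1, 1 and 5 FPKM) with 2 pseudocounts (1 and 0.1) and with or without the replicate number as a block, and the number of calls differed widely between them. Of the 13091 tested genes, 2833 had an unadjusted p under 0.05, and 143 an adjusted p under 0.01. The libraries of the strains did not overlap for 6818 tested genes, or 52.1%, where chance gives 33.3% for 2 against 2. This held for all 1095 called genes.

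Depth per library is not given in the sources used here. Low values rise in steps of what 1 fragment is worth. Among genes with 1 transcript of 950 to 1050 nt and values above 0 and below 0.6 FPKM (292 to 308 per library), the spacing from 0.02 to 0.2 FPKM that best fit the values was 0.0848 and 0.0842 FPKM per 1 kb in the control and 0.0876 and 0.0852 in the mutant libraries. A value of 1 FPKM for such a transcript thus rests on about 11.4 to 11.9 fragments. Against control replicate 1 the other libraries had 1.007, 0.968 and 0.995 times its depth by this spacing, with 95% bootstrap intervals (1000 draws of genes) of 0.986 to 1.036, 0.93 to 1.918 and 0.975 to 1.024; the wide interval of mutant replicate 1 leaves its depth open. In 3 simulated spacings the largest error was 0.33%. This estimate was chosen after the low values were seen. Tested on simulated data for the comparison of the strains (13091 genes), the test recovered 17% of 100 genes changed 2-fold and 65% of 100 changed 4-fold, and 3 of 85 calls were false. No other genes were changed, directions were random and the noise was independent between genes. In the data 1095 genes were called, 956 of them lower, so the shares recovered and false there may differ. Of 200 simulated lists with no shift, 9 passed camera at an unadjusted threshold of 0.05. These lists were random and the noise was independent between genes, so the rate for lists of genes that vary together was not measured.

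Before the data were examined, 30 gene lists with 678 genes were fixed, of which 668 matched the files and 606 were tested. mccc-2 and hmgl-1 were among those that did not match. Lists were tested with camera of limma (preset inter-gene correlation 0.01, adjusted over 30 lists), with camera using an estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction. Of 8 lists called with the preset correlation, none was called with an estimated correlation or with fry. The estimated correlation gave all 8 a limma camera adjusted p of 0.852, also the major sperm proteins, of which all 28 tested genes were called. The lowest fry adjusted p was 0.146. With 2 residual degrees of freedom these tests had little means to call a list, so a miss in them says little about a single list. The median, mean and test direction differed in sign for the lists of biotin-dependent enzymes, beta-oxidation, oxidative stress and neurons, none of them called. Families of genes, by the letters before the hyphen and with at least 10 tested members, were compared with other tested genes by Fisher's exact test, two-sided. That test counts genes as independent, which members of a family need not be, so all family p-values are too small by an unknown amount.

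The genes named in the text follow a rule fixed before the data were examined. It takes all tested members of the lists of the propionate shunt, B12-dependent propionate breakdown and branched-chain amino acid breakdown, and nhr-10, nhr-68 and nhr-114. It also takes the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 FPKM (5 CPM in the plan) and no overlap of the groups. To these it adds up to 4 called members per other list with the smallest p, or 2 members for a list that passed with none called, and the 2 called members with the smallest p of each enriched family. F44D12.7, as the copy of a named gene, and phy-2, as an example of a gap between the controls, were added after their values were seen. So were the genes named only under the other observations at the end. Names were matched by gene identifier for 18776 of 20535 genes, and 20337 identifiers were in the annotation. Coordinates are those of the identifiers in the WBcel235 annotation (Ensembl release 115); the build the authors used is not given in the sources used here.

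Alternatives fixed before the data were examined were no filter, a minimum of 5 FPKM, the replicate number as a block, leaving out vitellogenins and major sperm proteins, leaving out each library in turn, and the other set tests. Alternatives added later were a minimum of 0.1 FPKM, a pseudocount of 0.1, median-of-ratios, upper-quartile and quantile normalization, a robust variance model, leaving out 74 sperm genes, and the combinations of filter, pseudocount and block described above. The alternatives that need counts were not run.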

Results

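RNA of whole young adult animals of the nematode Caenorhabditis elegans was profiled by RNA-seq in 2 strains. The control strain, VL749, carries the integrated reporter wwIs24, in which the promoter of acdh-1 drives green fluorescent protein and which the labels list together with unc-119. The mutant strain, VL1080, carries the same reporter and the allele ww4 of mccc-1. Each strain had 2 libraries, named as biological replicates, from at least 200 animals each. All animals had grown on nematode growth medium with the bacterium Comamonas aquatica DA1877, a food that supplies vitamin B12, and were collected 70 h after hatching at 20 °C. The files gave 20535 genes per library in FPKM (fragments mapped to a gene, scaled by its transcript length and by the mapped fragments of the library). The FPKM values summed to 786436 and 780720 in the control libraries and to 741399 and 770579 in the mutant libraries, and 17185, 17056, 17182 and 16925 genes were above 0. Total depth is not given in the sources used here and was only estimated, from the spacing of low values. Across the tested genes Pearson's r of log2 values was 0.978 between the controls, 0.981 between the mutants, and 0.930 to 0.965 between strains, with genes rather than samples as the points.

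The comparison asks how the mccc-1(ww4) mutation affects gene expression. mccc-1 encodes a subunit of methylcrotonyl-CoA carboxylase, a biotin-dependent enzyme of leucine breakdown. The RNA of mccc-1 itself (WBGene00009319; chromosome IV, 9884570 to 9887151, forward strand, protein-coding, WBcel235 annotation) did not pass the test. It stood at 104.19 and 105.26 FPKM in the control libraries and at 100.43 and 100.33 FPKM in the mutant libraries. The means were 104.73 ± 0.757 and 100.38 ± 0.0707 FPKM (SD, n = 2 each), and the log2 fold change was -0.06 (SE 0.11, limma adjusted p = 0.821). The labels do not give the lesion of ww4, so this level neither bears out nor contradicts the genotype labels.

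Some genes of branched-chain amino acid breakdown and of the propionate shunt, and the folate transporter gene folt-2, were higher in the mutant, and most tested genes of sperm were lower. Of 13091 tested genes, 1095 changed between the strains; 956 of them were lower in the mutant and the others higher (limma-trend, Benjamini-Hochberg adjusted p under 0.05). Among these, 1019 changed at least 2-fold on the log2(FPKM + 1) scale, 89 higher and 930 lower. All 28 tested major sperm protein genes were among the genes that fell. The count of changed genes depended on the filter for low values, which was chosen after these counts were seen. With no filter beyond a value above 0, or with a minimum of 0.1 FPKM, 4 genes changed. These were C09B8.4, unc-119 and folt-2, which were higher, and Y43C5A.2, which was lower. Without control replicate 2, mutant replicate 1 or mutant replicate 2, the count was 465, 393 and 711, and it was 726 after quantile normalization. Without control replicate 1 it was larger. With the replicate number as a block, which the labels do not say marks a batch, it was 1803, and 352 of these were higher.

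**Figure D1:**
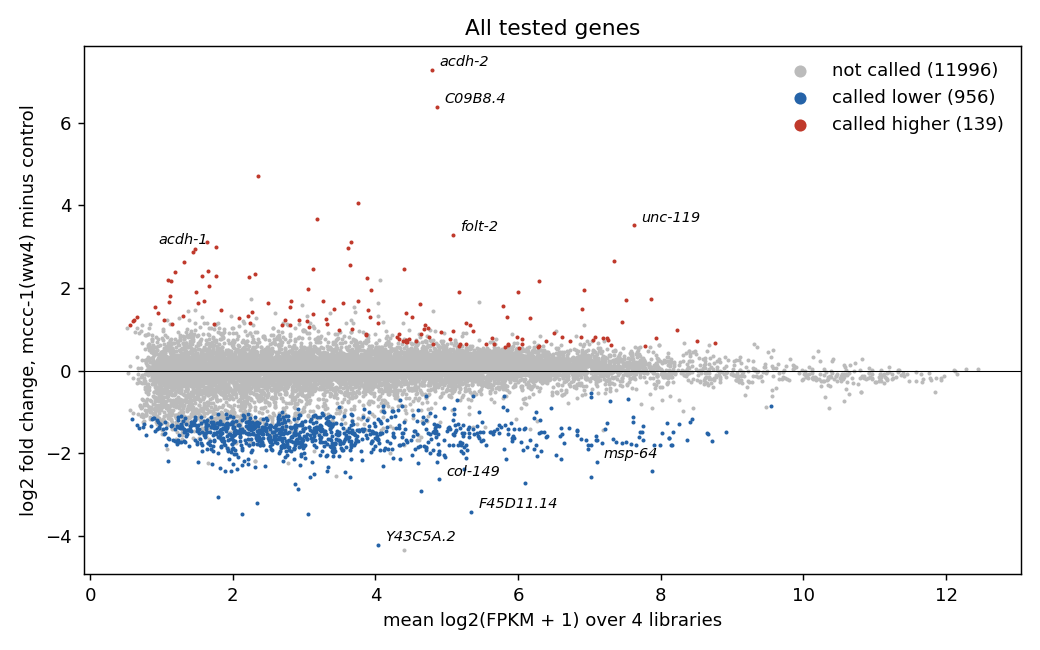
Each point is a tested gene, with the mean log2(FPKM + 1) over the 4 libraries on the x axis and the log2 fold change, mutant minus control, on the y axis. The 956 genes called lower are blue and the other called genes, which were higher, are red; acdh-2 has the highest fold change, at 7.27.

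Of the 11 tested genes of branched-chain amino acid breakdown, 3 rose, none fell and 8 did not pass the test; 4 rose when adjusted over the list alone. ivd-1, which encodes isovaleryl-CoA dehydrogenase, the step before methylcrotonyl-CoA carboxylase in leucine breakdown, rose from 88.1 ± 0.566 to 157 ± 7.85 FPKM (SD, n = 2 each; log2 fold change 0.82, SE 0.12, limma adjusted p = 0.0128). The acyl-CoA dehydrogenase gene acdh-9 rose from 60.5 ± 1.103 to 238 ± 30.2 FPKM (1.96, SE 0.13, limma adjusted p = 0.00395). The thiolase gene kat-1 rose from 116.77 ± 20.2 to 262 ± 9.64 FPKM (1.17, SE 0.15, limma adjusted p = 0.0111). bcat-1, the branched-chain aminotransferase gene, had 118 ± 5.72 FPKM in the control and 165.33 ± 0.205 FPKM in the mutant and missed the threshold (limma adjusted p = 0.0561). The genes of the branched-chain ketoacid dehydrogenase, bckd-1A, bckd-1B, dbt-1 and dld-1, had log2 fold changes of 0.00, -0.10, 0.27 and 0.01, and those of acdh-3 and ard-1 were 0.19 and 0.18; none of these passed. As a set the list was higher than other genes (median log2 fold change 0.19, limma camera adjusted p = 0.0188), with adjusted p = 0.852 with an estimated correlation. That call was lost without control replicate 1 (adjusted p = 0.0538), without mutant replicate 2 (0.11) and after quantile normalization (0.0956).

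The propionate shunt is a B12-independent route of propionate breakdown. Of its 5 tested genes, 2 rose and 3 did not pass, with the same counts when adjusted over the list alone. acdh-1 (WBGene00016943; chromosome I, 6497436 to 6499560, forward strand), the acyl-CoA dehydrogenase gene whose promoter is in the reporter, was at 0.07 and 0.36 FPKM in the control libraries and at 8.27 and 8.79 FPKM in the mutant libraries (log2 fold change 2.98, SE 0.26, limma adjusted p = 0.00591). For a transcript of about 1 kb, 1 fragment was worth about 0.0842 to 0.0876 FPKM, so the control values of acdh-1 lie near the limit of detection. ech-6, an enoyl-CoA hydratase gene, rose from 109.87 ± 1.202 to 191 ± 21.3 FPKM (0.79, SE 0.13, limma adjusted p = 0.0173; 0.07 without control replicate 2). hach-1, hphd-1 and alh-8, which encode the later steps, had log2 fold changes of 0.13, 0.09 and 0.35. The list was higher as a set (median 0.35, limma camera adjusted p = 0.0194; adjusted p = 0.852 with an estimated correlation). This call was lost without control replicate 1 (0.0736), mutant replicate 1 (0.113) or mutant replicate 2 (0.39), and after quantile normalization (0.0677).

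acdh-2 (WBGene00015894; chromosome II, 5544778 to 5547492, reverse strand), an acyl-CoA dehydrogenase gene related to acdh-1, was at 0.41 and 2.5 FPKM in the control and at 397.46 and 296.01 FPKM in the mutant libraries (log2 fold change 7.27, SE 0.40, limma adjusted p = 0.00147). Reads shared between acdh-1 and acdh-2 could have been split by the authors' quantification. With acdh-9, 3 of the 12 tested acdh genes were higher, against 1.04% of other genes (Fisher's exact test, two-sided, adjusted p = 0.0107 over 111 families and both directions). Another 3 of the 12, acdh-8 among them, were lower, against 7.29% of other genes (adjusted p = 0.824), so the family holds calls in both directions.

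In the B12-dependent route of propionate breakdown none of the 6 tested genes changed by limma, also when adjusted over the list alone. The log2 fold changes of pcca-1, pccb-1, mce-1, mmcm-1, mmaa-1 and mmab-1 were -0.31, -0.20, -0.58, -0.28, 0.02 and 0.17 (limma camera adjusted p = 0.49). mce-1 passed as lower without control replicate 1 (limma adjusted p = 0.0321). Of 23 genes of the methionine cycle and of folate metabolism, folt-2 (WBGene00018138; chromosome V, 2872465 to 2875600, reverse strand), a folate transporter gene, was the only one called, also over the list alone. It rose 10.7-fold, from 9.85 ± 0.467 to 105 ± 4.98 FPKM (log2 fold change 3.29, SE 0.14, limma adjusted p = 0.000341). The list as a whole did not pass (median 0.05, adjusted p = 0.68). The nuclear receptor genes nhr-10, nhr-68 and nhr-114, regulators of the propionate shunt and of the response to low B12, had log2 fold changes of -0.32, 0.74 and 0.60 and did not pass (limma adjusted p = 0.519, 0.259 and 0.165), nor did the list of 12 B12 and lipid receptors and partners (median 0.29, adjusted p = 0.0673; 0 called, also over the list alone). That list passed as higher with no filter beyond a value above 0 (adjusted p = 0.0381) and with a minimum of 0.1 FPKM (0.0431).

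**Figure D2:**
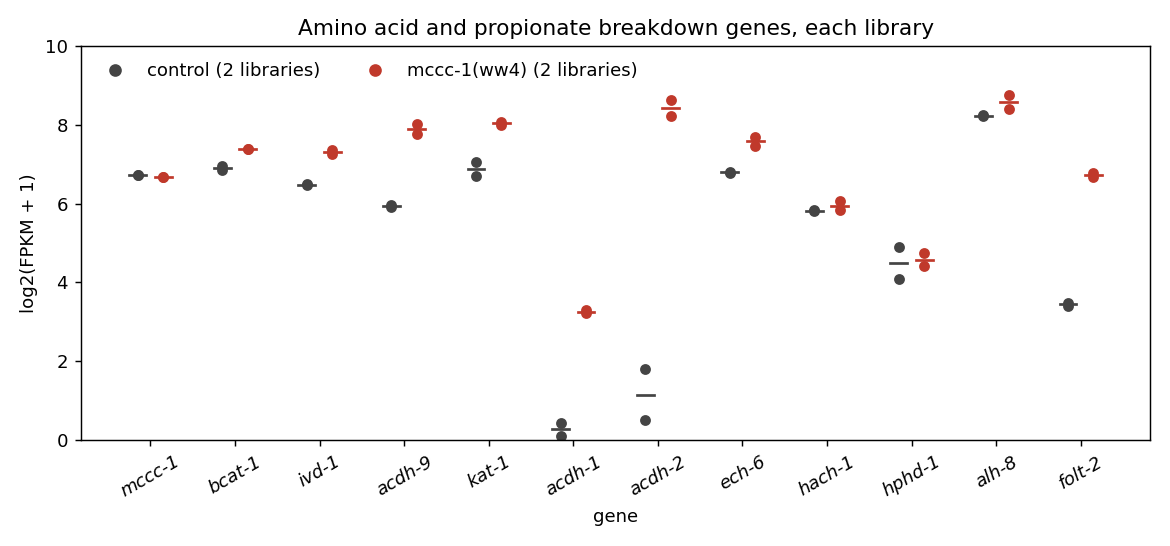
Points are single libraries and bars are means of log2(FPKM + 1) on the y axis, for 12 genes on the x axis, 2 control libraries in grey and 2 mccc-1(ww4) libraries in red. acdh-1, acdh-2 and folt-2 show the widest gaps between the strains, with log2 fold changes of 2.98, 7.27 and 3.29, while mccc-1 has a log2 fold change of -0.06.

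The other genes with the largest rises came from no fixed list. unc-119 (WBGene00006843; chromosome III, 10902641 to 10908935, forward strand), a neuronal gene that the labels name in the reporter of both strains, rose 11.6-fold, from 57.4 ± 3.76 to 668 ± 4.57 FPKM (log2 fold change 3.52, SE 0.12, limma adjusted p = 0.000183). C09B8.4 was at 2.03 and 2.34 FPKM in the control and at 303.17 and 232.09 FPKM in the mutant libraries (6.39, SE 0.18, limma adjusted p = 9.44e-05). F59A7.2, the glucuronosyltransferase gene ugt-53 and the short-chain dehydrogenase gene dhs-25 had log2 fold changes of 3.67, 3.11 and 2.66 (limma adjusted p = 0.00395, 0.00777 and 0.00591). K11H12.4 had one of 2.96 (limma adjusted p = 0.0198), which was 0.0709 without mutant replicate 1. nspc-5 was listed at 0 in both control libraries and at 29.46 and 21.2 FPKM in the mutant libraries, but belongs to a family of similar genes and is uncertain. F44D12.3 was at 9.6 and 0.03 FPKM in the control and at 49.36 and 59.8 FPKM in the mutant libraries (limma adjusted p = 0.0484), while its near-identical copy F44D12.7 went from 320 ± 45.6 to 53.4 ± 16.09 FPKM. Both values are uncertain, because the copies share reads; their sum was 325 ± 38.8 FPKM in the control and 108 ± 23.5 FPKM in the mutant. The call of F44D12.3 was also lost without mutant replicate 1 or 2 (limma adjusted p = 0.132 and 0.133), at a minimum of 5 FPKM (0.0501), without vitellogenins and major sperm proteins (0.051), with a pseudocount of 0.1 (0.13), with median-of-ratios, upper-quartile or quantile normalization (0.0602, 0.0607 and 0.0672) and with a robust variance model (0.317).

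Sperm genes stood lower in the mutant, and the germline, oocyte and embryo lists did not fall with them. All 28 tested genes of the major sperm proteins, the cytoskeletal proteins of nematode sperm, fell, over all genes and when adjusted over the list alone (median log2 fold change -1.69, limma camera adjusted p = 3.82e-22; adjusted p = 0.852 with an estimated correlation). Summed over 29 genes, a sum less affected by reads shared among these near-identical genes, their level was 10798 ± 333 FPKM in the control and 3565 ± 1056 FPKM in the mutant (SD, n = 2 each), 3.03-fold lower. msp-64, msp-142, msp-38 and msp-40 had log2 fold changes of -2.21, -1.89, -1.86 and -1.81. Of 22 other sperm genes, 15 fell and 7 did not pass, and 20 fell when adjusted over the list alone (median -1.41, limma camera adjusted p = 1.14e-13, and 0.852 with an estimated correlation). The mutant libraries differed here, with 5 of the 22 genes at least 2-fold higher in mutant replicate 2 than in mutant replicate 1 and 0 the other way. The major sperm protein sum was 2818 and 4311 FPKM in mutant replicates 1 and 2, and 11033 and 10562 FPKM in control replicates 1 and 2. gsp-3, a sperm phosphatase gene, went from 58.3 ± 0.106 to 13.995 ± 3.995 FPKM (-2.01, SE 0.20, limma adjusted p = 0.00687), and spe-11, which encodes a protein that sperm bring to the embryo, from 61.9 ± 11.3 to 21.1 ± 3.62 FPKM (-1.51, SE 0.19, limma adjusted p = 0.0103). htas-1 and ssp-10 had log2 fold changes of -1.79 and -1.42, and spe-54 and ssp-34 of -1.70 and -1.68. Genes called lower were enriched in the msp, spe and ssp families, with 28 of 28, 11 of 26 and 7 of 12 (Fisher's exact test, two-sided, adjusted p = 2.31e-30, 9.19e-05 and 0.000459). They were depleted among nhr genes (1 of 151, adjusted p = 0.0107 by the same test). Genes of a family can share reads and vary together, so these p-values are too small by an unknown amount.

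Of 22 oocyte and eggshell genes, 2 rose over all genes and 19 when adjusted over the list alone (median 0.50, limma camera adjusted p = 8.26e-07; adjusted p = 0.852 with an estimated correlation). They were spn-4, from 344 ± 45.3 to 549 ± 32.2 FPKM, and mex-6, from 177 ± 15.6 to 268 ± 21.7 FPKM, genes of RNA-binding proteins loaded into the egg (limma adjusted p = 0.0403 and 0.043). Without control replicate 2, mutant replicate 1 or mutant replicate 2 these p-values were 0.263, 0.142 and 0.0767 for spn-4 and 0.265, 0.152 and 0.0605 for mex-6, and mex-6 was also lost without control replicate 1 (0.0571). Both calls were lost with median-of-ratios scaling (0.0773 and 0.0645) and with upper-quartile scaling (0.0974 and 0.0806), and that of mex-6 with quantile normalization (0.0506) and a pseudocount of 0.1 (0.051). None of the 23 germline, 8 embryo, 6 vitellogenin or 13 molting cycle genes tested passed, over all genes or over the list alone. The embryo list was fixed with 20 genes, and most of them lay below the filter, so its test rests on a minority of its members. Their medians were 0.03, 0.45, -0.08 and -0.09 (limma camera adjusted p = 0.691, 0.203, 0.648 and 0.49). The embryo list passed as higher with a minimum of 0.1 FPKM (adjusted p = 0.0431).

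**Figure D3:**
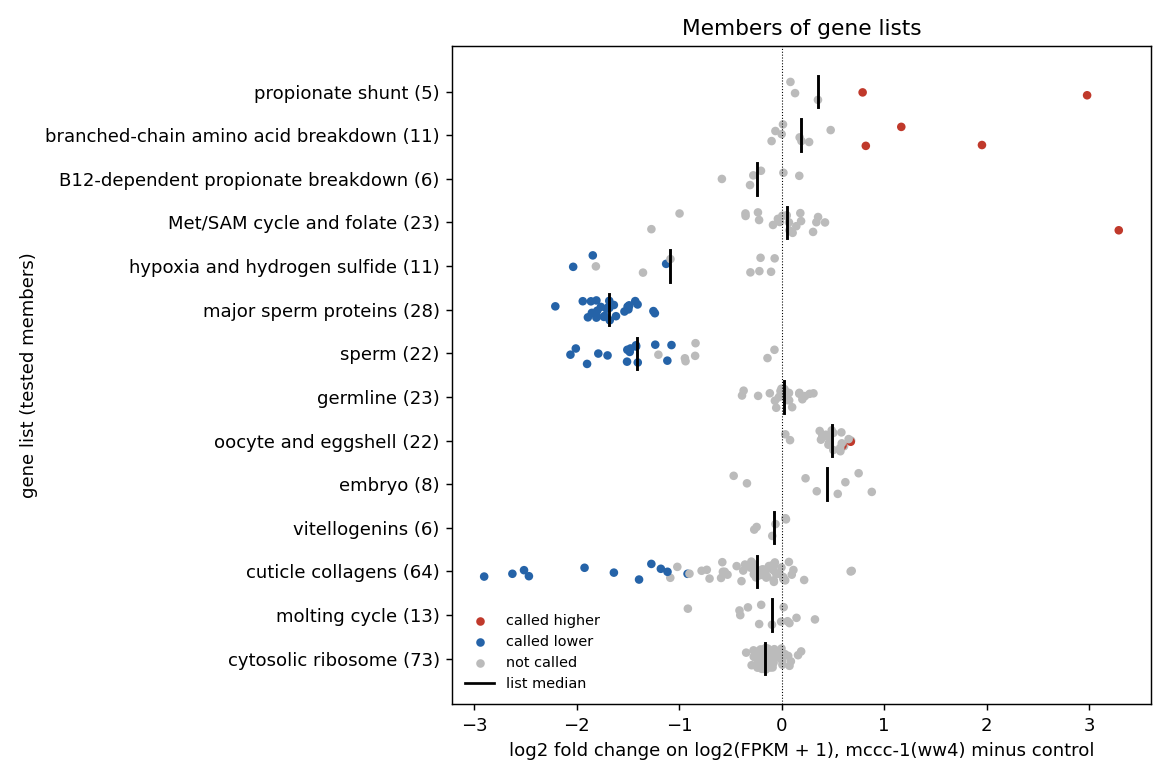
Each point is the log2 fold change (x axis, on log2(FPKM + 1), mutant minus control) of a tested member of 14 gene lists (y axis), and the black bar is the list median. The 28 major sperm protein genes lie between -2.21 and -1.24, while the germline list has a median of 0.03.

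Cuticle collagens, the structural proteins of the worm's exoskeleton, also held lower genes. Of 64 tested, 11 fell and 53 did not pass; 15 fell when adjusted over the list alone (median -0.24, limma camera adjusted p = 0.000214; adjusted p = 0.852 with an estimated correlation; 0.125 without control replicate 1). The col family, grouped by name, did not pass, with 14 of 93 genes lower (15.1% against 7.25% of other genes; Fisher's exact test, two-sided, adjusted p = 0.202). The replicates differed in this list, with 18 of the 64 genes at least 2-fold higher in control replicate 1 than in control replicate 2 and none the other way, and 14 at least 2-fold higher in mutant replicate 1 than in mutant replicate 2 and 2 the other way. col-149 went from 73.2 ± 12.8 to 10.9 ± 0.997 FPKM (log2 fold change -2.63, SE 0.17, limma adjusted p = 0.00395). col-133, col-7, col-180 and col-12 had log2 fold changes of -2.90, -2.51, -2.47 and -1.39. Of 11 genes that respond to hypoxia or hydrogen sulfide, 3 fell and 8 did not pass; 5 fell when adjusted over the list alone (median -1.08, limma camera adjusted p = 0.00382; adjusted p = 0.852 with an estimated correlation). These were cysl-2, of the cysteine synthase family, from 75.3 ± 35.98 to 19.1 ± 0.997 FPKM, F22B5.4, from 20.98 ± 11.9 to 4.03 ± 1.17 FPKM, and the nuclear receptor gene nhr-57, from 6.38 ± 1.04 to 2.38 ± 0.375 FPKM (limma adjusted p = 0.0177, 0.0285 and 0.0418). Control replicate 2 stood apart in this list, with 5 of the 11 genes at least 2-fold above control replicate 1 and none the other way, such as phy-2, not called, at 97.4 against 14.99 FPKM. Without control replicate 2 the list median was -0.50. The calls of the 3 genes were lost without mutant replicate 1 (0.0629, 0.112 and 0.128), those of F22B5.4 and nhr-57 without control replicate 2 (0.0559 and 0.199) and after quantile normalization (0.0519 and 0.0823), and that of nhr-57 without mutant replicate 2 (0.166) and at a minimum of 5 FPKM (0.0649).

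The called gene with the deepest fall on the log2(FPKM + 1) scale was Y43C5A.2 (WBGene00012782; chromosome IV, 10269883 to 10272701, forward strand), from 69.7 ± 5.20 to 2.80 ± 0.156 FPKM, 24.9-fold lower (log2 fold change -4.22, SE 0.17, limma adjusted p = 0.000341). It lies 0.383 Mb from mccc-1. adh-1, an alcohol dehydrogenase gene, went from 182.64 ± 72.5 to 27.7 ± 15.5 FPKM (-2.73, SE 0.41, limma adjusted p = 0.0142; 0.0744 with a robust variance model). drd-10, F45D11.14 and W06G6.17 had log2 fold changes of -3.48, -3.42 and -2.74. ZK546.3 and F59A6.8, annotated as pseudogenes and so possibly sharing reads with other genes, had -3.46 and -2.86. C07B5.8 had -3.21, and its call was lost with a pseudocount of 0.1 (limma adjusted p = 0.0653).

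The remaining lists held few or no calls, and only the ribosome list passed as a set. None of the 73 genes of the cytosolic ribosome passed, over all genes or over the list alone, but the list was lower as a set (median -0.16, limma camera adjusted p = 0.0236; adjusted p = 0.852 with an estimated correlation). rps-17 and rpl-26, its genes with the smallest p, had log2 fold changes of -0.29 and -0.35. With the replicate number as a block the list did not pass (limma camera adjusted p = 0.205). The ribosome call was lost without control replicate 1 (0.86) and after quantile normalization (0.533), and without mutant replicate 1 the test direction turned (median -0.03, adjusted p = 0.709).

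In fatty acid synthesis, desaturation and elongation 1 of 19 genes changed, acs-1, an acyl-CoA synthetase gene, which rose from 127 ± 15.2 to 195 ± 17.6 FPKM (limma adjusted p = 0.0458), with 4 higher and 2 lower when adjusted over the list alone. Its call was lost without control replicate 2, mutant replicate 1 or mutant replicate 2 (0.269, 0.0789 and 0.135), with median-of-ratios (0.0911), upper-quartile (0.115) or quantile normalization (0.0559), with a pseudocount of 0.1 (0.0547) and without sperm genes (0.0511). In beta-oxidation kat-1 and the thiolase gene acaa-2 rose and acdh-8 fell among 27 genes (2 higher and 2 lower over the list alone). acaa-2 went from 100.92 ± 3.70 to 178.45 ± 7.74 FPKM and acdh-8 from 49.6 ± 6.85 to 12.8 ± 2.92 FPKM (limma adjusted p = 0.0132 and 0.00777), and acaa-2 missed the threshold without control replicate 2 (0.0579).

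Of 13 heat shock genes, hsp-70 and F44E5.5 fell, and the same number fell over the list alone. Control replicate 2 stood apart in this list, with 7 of the 13 genes at least 2-fold above control replicate 1 and none the other way. In the mutant, 3 genes were at least 2-fold higher in replicate 2 than in replicate 1, and 1 the other way. With the replicate number as a block the list passed as lower (limma camera adjusted p = 0.0247). In control replicate 2 hsp-70 was at 57.57 FPKM, against 14.91 in control replicate 1 and 4.4 and 3.88 in the mutant libraries (limma adjusted p = 0.0372). The hsp-70 call was lost without mutant replicate 1 or 2 (0.109 and 0.105), after quantile normalization (0.0624) and with a robust variance model (0.114). F44E5.5 (limma adjusted p = 0.0456) was lost without control replicate 2, mutant replicate 1 or mutant replicate 2 (0.139, 0.075 and 0.14) and with a pseudocount of 0.1 (0.0548). The heat shock list passed as lower without control replicate 1 (adjusted p = 0.00304), where control replicate 2 is the control left.

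Of 19 cytochrome P450 and xenobiotic response genes, ugt-44 rose and cyp-35A2 and cyp-37B1 fell (1 higher and 5 lower over the list alone), with log2 fold changes of 0.98, -1.48 and -1.36. The call of ugt-44 was lost without any of the 4 libraries (limma adjusted p = 0.0519 to 0.155), that of cyp-35A2 without mutant replicate 1 (0.097), and that of cyp-37B1 without mutant replicate 1 or 2 (0.123 and 0.129) and after quantile normalization (0.0694). Without control replicate 2 this list passed as lower (adjusted p = 0.003). nit-1 fell among 23 oxidative stress genes (1 over the list alone; log2 fold change -1.25, limma adjusted p = 0.0338), and was lost without control replicate 2, mutant replicate 1 or mutant replicate 2 (0.161, 0.148 and 0.105) and after quantile normalization (0.0671). irg-5 fell among 26 innate immunity genes (2 higher and 3 lower over the list alone; -1.401, limma adjusted p = 0.034), and was lost without control replicate 2 (0.0657), after quantile normalization (0.0549) and with a robust variance model (0.0503). The innate immunity list passed as higher without control replicate 1 (0.0379), in which 8 of the 26 genes were at least 2-fold above control replicate 2 and 3 the other way. The cathepsin gene cpr-1 fell among 18 intestine genes (1 over the list alone; -1.90, limma adjusted p = 0.0118).

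No gene was called, over all genes or over the list alone, among 25 of the tricarboxylic acid and glyoxylate cycles, 40 of the respiratory chain, 11 of the mitochondrial and 16 of the endoplasmic reticulum unfolded protein response, 5 biotin-dependent enzymes, 13 of the insulin pathway and DAF-16 class, 22 neuronal and 18 muscle genes. Their medians lay between -0.16 for muscle and 0.11 for the endoplasmic reticulum list, and none passed by limma camera, although the respiratory chain passed as lower without mutant replicate 2 (adjusted p = 0.0042) and with no filter beyond a value above 0 (0.048).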

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

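The low-value minimum of 0.1 FPKM, the pseudocount of 0.1, the 3 scalings, the robust variance model, the removal of sperm genes and all combined settings were chosen after seeing the data. The planned count-based alternatives (RLE and upper-quartile factors, and 2 other count tools, also for families) were not run, because the files hold no counts. The 1095 called genes that an alternative tested kept their direction in all 15 alternatives that changed 1 choice. This is little evidence of robustness, because the groups did not overlap for any called gene. Leaving out a library, or changing the filter, pseudocount, block or variance model, could thus not turn a direction. With no filter beyond a value above 0, 4 genes changed (3 higher, 1 lower, 4 at least 2-fold) and 0 families passed; a minimum of 0.1 FPKM gave 4, 3, 1, 4 and 0. With 18934 and 16857 genes tested, the prior degrees of freedom fell from 4.65 to 2.22 and 2.56; the cause was not tested further. Either of these filters gave 4 genes with a pseudocount of 0.1 and 0 with the block, with either pseudocount; the combinations with a minimum of 1 or 5 FPKM gave 766 to 1636. Quantile normalization gave 726 changed (603 lower, 677 at least 2-fold), 5 lists and 7 families, and the cause was not tested. Leaving out sperm genes gave 2 families enriched among calls, acdh (higher) and spe (lower, 6 of 16), with adjusted p = 0.0375 for each. The other alternatives that changed 1 choice, leaving aside the block and the left-out libraries, gave 830 to 1256 changed genes. Camera with an estimated correlation called 0 lists and fry 0 lists, against 8, but with 2 residual degrees of freedom both had little means to call a list. mccc-1 was not called in any alternative (log2 fold change -0.14 to -0.05, adjusted p = 0.597 to 0.958).

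Replicate numbers are shared between the strains, but the labels do not say that they mark a batch. With 2 pairs the correlation of deviations (0.176) does not decide it, so the libraries were not treated as paired. By at least 2-fold, collagens were higher in replicate 1 of both strains (18 genes against 0 in the control, 14 against 2 in the mutant). Heat shock genes were higher in replicate 2 of both (7 against 0, and 3 against 1). Hypoxia genes shifted in the control only (5 against 0) and sperm genes in the mutant only (5 against 0). The block raised the prior degrees of freedom to 13.36, so a shared replicate effect stays open. With the replicate number as a block, 1803 genes changed (352 higher, 1451 lower), the ribosome list lost its call (adjusted p = 0.205), the heat shock list passed as lower (0.0247), and no other list call changed. Leaving out 1 library leaves a strain with 1 library, which is then assumed to vary like the other strain. The ranges were 393 to 1324 genes changed, 37 to 244 higher, 356 to 1080 lower and 374 to 1217 changed at least 2-fold, with the lowest counts without mutant replicate 1 and the highest without control replicate 1. Fewer samples enter these fits. Lists called ranged from 6 to 9 and families from 3 to 6. The cytosolic ribosome list turned in test direction without mutant replicate 1 (median -0.026, adjusted p = 0.709; the medians ranged from -0.2698 to -0.026 over the left-out libraries), and the cause was not tested. Of 76 named genes, some were not called in the main fit and so had no call to lose. With no filter or with 0.1 FPKM, 50 lost their call, and only C09B8.4, unc-119, folt-2 and Y43C5A.2 kept theirs. Some calls were also lost when 1 library was left out, most of them without mutant replicate 1, and at most 9 were lost in any other setting. A 2-fold change was recovered in 17% of simulated genes, so a gene not called is not shown to be unchanged.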

Other observations

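Tests of scaling for the sperm pattern, of genes called lower near mccc-1 and of the X chromosome were chosen only after the results they bear on were seen, as were the genes and chromosome comparisons of the next 2 paragraphs.

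Some called genes outside the lists were picked after their values were seen, and no test asked whether genes of their kind rose. sur-5, an acetoacetyl-CoA synthetase gene, went from 36.5 ± 11.137 to 165.2 ± 2.52 FPKM (SD, n = 2 each; log2 fold change 2.18, SE 0.20, limma adjusted p = 0.00591), and C05C10.3, a 3-oxoacid CoA-transferase gene, from 127 ± 23.2 to 422 ± 1.56 FPKM (1.73, SE 0.15, limma adjusted p = 0.00591). Acetoacetate is an end product of leucine breakdown, and these enzymes attach CoA to it. In the family of acyl-CoA synthetase genes named acs, 4 of 21 were lower and 1 higher (adjusted p = 0.924 and 1). The thiolase gene T02G5.7 went from 115.2 ± 14.7 to 199 ± 13.05 FPKM (0.79, limma adjusted p = 0.0214), and B0250.5, a 3-hydroxyisobutyrate dehydrogenase gene of valine breakdown, from 65.6 ± 8.49 to 123 ± 15.3 FPKM (0.90, limma adjusted p = 0.0187). hmgs-1, the 3-hydroxy-3-methylglutaryl-CoA synthase gene, was not called, at 13.6 ± 1.63 and 13.3 ± 0.170 FPKM (-0.02, limma adjusted p = 0.96). The ceramide synthase gene hyl-1 (2.56, limma adjusted p = 0.0053) and the serine palmitoyltransferase gene sptl-3 (0.96, limma adjusted p = 0.0155) were also higher.

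Calls were spread unevenly over the chromosomes (12 Fisher's exact tests, two-sided, adjusted together). Genes called higher made up 2.01% of 2432 tested genes on chromosome V against 0.842% elsewhere (odds ratio 2.42, adjusted p = 1.06e-05). Genes called lower made up 12.29% of tested genes on chromosome IV against 6.28% elsewhere (odds ratio 2.09, adjusted p = 3.31e-20) and 1.32% on the X chromosome against 8.27% elsewhere (odds ratio 0.149, adjusted p = 3.27e-33). They were also more frequent on chromosome I (9.36% against 6.93%, adjusted p = 0.000301) and less frequent on chromosomes V (5.76% against 7.71%, adjusted p = 0.00182) and III (6.10% against 7.58%, adjusted p = 0.0348); the other 6 tests did not pass. Neighbouring genes are not independent, so these p-values are too small by an unknown amount.

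Transcripts of sperm were lower in the mutant while the germline, oocyte and embryo lists were not. After median-of-ratios scaling the sperm list had a median log2 fold change of -1.46. The factors lay between 0.966 and 1.053, so this rescaling could move the list only a little and decides nothing by itself. A scaling factor common to all genes is argued against by the main fit. There the median log2 fold change was 0.046 over all tested genes and -1.41 for the sperm list. A loss of germ cells of all kinds is argued against as well, since the oocyte and eggshell list had a median of 0.496 and the germline list one of 0.03. Among genes outside the sperm lists and families, those on the X chromosome, which carries few sperm genes, were called lower less often than autosomal genes (1.32% against 7.8%, odds ratio 0.158, 95% interval 0.0996 to 0.24, Fisher's exact test). This largely repeats the chromosome comparison above, since the X count was 23 of 1739 with and without the sperm genes. It cannot decide whether the pattern extends to sperm genes beyond the lists. An offset in stage between the strains stays open, because the embryo list and the oocyte list both had positive medians, the lower at 0.446. In the main fit only 8 of the 20 embryo genes were tested, and the embryo list missed the threshold (limma camera adjusted p = 0.203). With a minimum of 0.1 FPKM the embryo list passed as higher (adjusted p = 0.0431, median 0.279). An effect of the mccc-1 genotype on sperm number is also open, and no animals were counted here.

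unc-119 was 11.6-fold higher in the mutant. A rise of neuronal genes in general is argued against, since the 22 tested genes of the neuronal list, which does not hold unc-119, had a median log2 fold change of -0.00224. A change of the whole chromosome region around unc-119 is argued against too, since the 14 tested genes within 50 kb had a median of 0.115 (range -1.03 to 0.487) and 0 of them were called. Neighbouring genes cannot show a change confined to unc-119 itself, so that stays open. The reporter that both strains carry includes unc-119 beside the acdh-1 promoter, and a candidate explanation is a different number or activity of unc-119 copies in it; FPKM per gene do not separate transgene from native transcripts, so this was not tested.

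Variants linked to mccc-1 could differ between the strains whatever the mutation does. Genes called higher were not enriched within 2 Mb of mccc-1 (4 of 747 genes, odds ratio 0.487, 95% interval 0.131 to 1.28, Fisher's exact test, p = 0.195). This argues against an excess of rises among genes of that region. The test looks only at the position of the called genes, so it cannot decide whether a linked variant raised genes elsewhere. Genes called lower were more frequent within 2 Mb of mccc-1, at 15.7% against 6.83% (odds ratio 2.53). The odds ratio was 2.29 without the sperm lists and families, which need not hold all sperm genes. Of 71 windows of 4 Mb, taken every 1 Mb, that do not overlap this region, 2 had as high a share. These share 3 Mb, so they are 1 region, between 2 and 7 Mb on chromosome IV (at most 17.6%), which is on the chromosome of mccc-1 and may itself be linked. The highest share on another chromosome was 12.65%, on chromosome V between 14 and 18 Mb (Fisher's exact test against the mccc-1 region, p = 0.168, not adjusted for the choice of window). Whether linkage adds to the genes called lower cannot be told apart from the uneven spread of such genes over chromosome IV. Of the named genes with the largest changes, Y43C5A.2, with the deepest fall, lies 0.383 Mb from mccc-1 and F44D12.3, called higher, 0.135 Mb, so linked variants stay open for both. The rise of F44D12.3 is itself uncertain, because it shares reads with F44D12.7. Summed, the 2 copies were lower in the mutant (325 FPKM in the control and 108 FPKM in the mutant, log2 fold change -1.59). The mccc-1 genotype itself stays confounded with its linked region.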
